A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

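Transcript levels were measured in budding yeast with 1 Affymetrix YG_S98 expression array per sample, 8 arrays in all. Per the labels, 4 groups of 2 samples were profiled: a hem1 deletion strain with 5-aminolevulinic acid (ALA), the same strain without ALA, a wild type strain in normoxia and the wild type strain in hypoxia. ALA is the product of the enzyme that HEM1 encodes, the first step of heme synthesis, so the strain makes heme only when ALA is supplied. Per the labels, the hem1 strain was grown for 6 h in rich medium (YPD) with 250 µM ALA, washed, and inoculated in duplicate into 15 ml cultures with or without ALA for 16 h. The wild type was grown for 6 h and then in 15 ml for 12 h in air or in an anaerobic chamber. RNA was extracted with Trizol, per the labels' protocols. The labels do not say that the wild type samples of a group came from separate cultures. The p-values of genes therefore measure only the spread between these samples, which may be technical. Replicate numbers follow the order of the samples and pair nothing.

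The deposited values are signal intensities on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes. Its version is not given in the sources used here. The values themselves show the scaling: after removal of 2% of the probe sets at each end, the mean of each array lies between 500.42 and 500.58. Detection calls and probe-level files were not used here. Arrays scaled to 1 mean can shift against each other when many genes change. The median log2 signal over all probe sets other than controls was 0.40 higher without ALA than with it, 0.49 higher in hypoxia than in normoxia, and 0.23 higher in hem1 with ALA than in normoxia, while the mean was held equal. Differences are therefore also given after quantile normalization and after centring each array on its median.

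The table held 9335 probe sets, of which 60 were controls. Gene names came from the platform annotation, in which 6504 of the other 9275 probe sets had 1 gene, 328 had several and 2443 had none. All 6504 were matched by gene ID to the RefSeq gene table of assembly R64, which was used for names only. No coordinates are given, because no build is named for the array. A probe set entered the tests when its signal lay above the 30th percentile of its array on at least 2 of the 8 arrays. This left 7081 probe sets and 5284 genes. A gene with several probe sets is represented by the one with the highest mean.

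The log2 signals were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 8 arrays sharing 1 estimate of the spread (4 residual and 4.36 prior degrees of freedom), and moderated statistics with an intensity trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 7081 probe sets, and the threshold was an adjusted p of 0.05. Every adjusted p of a gene is from this limma fit. The contrasts were heme depletion (hem1 without ALA minus with ALA), hypoxia (hypoxia minus normoxia), the difference of these responses, and the difference of the control cultures (hem1 with ALA minus normoxia). The treatment contrasts share no arrays. A group whose arrays both lay at or below their 30th percentile is called dim, and a fold against it is given as "at least", the ratio to the mean over its arrays of the higher of that percentile and the measured signal. The same bound is given where only 1 of the 2 arrays of the lower group passed its percentile, a choice made after the data were seen.

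In all, 29 gene lists were fixed before the data were examined and tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists. The adjusted p rose with the estimate even for lists whose estimated correlation lay below 0.01, such as the Hap1 genes (-0.048). Failing with the estimate is therefore not by itself a sign of correlated genes. With the preset, camera takes its degrees of freedom from the number of genes, so its p treats genes as replicates. With the estimate they are limited to the 4 residual ones, so that p reflects the few arrays. Lists of seripauperins, hexose transporters and cytosolic ribosomal proteins hold near-identical copies, so their single members are uncertain. The lists share some genes. The list called sterol uptake here also holds regulators of uptake, such as UPC2, and the sterol esterification genes ARE1 and ARE2. Named genes were chosen by a rule also fixed before the data were examined: for each treatment, the 6 largest rises and 6 largest falls whose arrays did not overlap, up to 2 members of each list per direction with the smallest adjusted p, and 25 genes given whatever their values. For the difference of the responses the 6 largest in each direction were taken, and for the control cultures the 4 largest in each direction with the strain marker and mating-type genes. Not every list member taken by the rule is printed. The 25 genes are given for these contrasts too, a choice made after the data were seen.

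The procedure was tested on simulated data made from the arrays' own means and spread. A log2 change of 1 was recovered for 43.5% of changed probe sets in the heme contrast, 49.2% in the hypoxia contrast, 42.9% for the control cultures and 12.1% for the difference of the responses. For a log2 change of 2 the shares were 87.7%, 89.1%, 92.1% and 73.0%. Of the unchanged probe sets between 2 and 6 were called in each contrast. In the simulation small changes were often missed, in the difference of the responses above all. Only 61 to 66 probe sets were changed per size and contrast, whereas 49.9% and 55.8% of probe sets were called in the real treatment contrasts. With so few changes the adjustment is stricter, so these shares do not measure recovery in the real contrasts. The number of arrays limits the precision.

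Replicate arrays correlated at 0.976 to 0.985 (Pearson's r of log2 signal across probe sets, which are not independent), and no pair was identical. The alternatives tried were quantile normalization, median centring, no filter or a stricter one, a floor or an offset for low signals, other variance models, fits on only the groups compared, 1 probe set per gene, an estimated correlation, and each array left out in turn. Scaling to the 9 hybridization spike probe sets, and leaving out the 2 arrays with high 18S control signal, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.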

Results

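The study profiled the transcripts of yeast under 2 treatments. ALA was withheld from a strain labelled as a hem1 deletion, and oxygen, which heme synthesis needs, was removed from a wild type strain. The labels name only the samples without ALA as heme deplete, and the arrays do not measure heme. The data are 8 arrays in 4 groups of 2, with median signals of 98.1 to 158.9 per array and 30th percentiles of 26.6 to 48.7. All signals are MAS5 values and n = 2 for each group.

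The HEM1 probe set does not single out the hem1 strain. Its signal was 460 and 608 with ALA, 849 and 696 without ALA, 707 and 683 in normoxia, and 1413 and 1613 in hypoxia. It rose by 0.54 on the log2 scale without ALA (adjusted p = 0.0422), a call lost with median centring (0.541) and quantile normalization (0.128). Where this probe set lies relative to the deleted part is not known here, so it checks nothing, and the text speaks of arrays labelled hem1. LEU2, a leucine synthesis gene often used as a strain marker, was at least 59.4-fold higher in hem1 with ALA (1855 ± 241, SD) than in normoxia (25.02 ± 16.05, where 1 of 2 arrays lay above its 30th percentile), with an adjusted p of 2.0e-04. URA3 and LYS2 were below 10 on every array. All 4 genes specific to the MATalpha mating type were bright in both control cultures, and none of them differed between these.

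The first comparison asks what heme depletion does to transcript levels. Without ALA, most anaerobic cell wall genes and stress genes and 5 of 8 sterol uptake genes rose, and most genes for ribosomal proteins and ribosome assembly fell. By estimated log2 difference, a ranking that for dim genes rests on signals in the background, the rises at the top were SIP18, a gene known from salt and drying stress, at 1886 ± 145 against a dim 29.2 ± 9.1 (at least 51.9-fold), SPG4, known from stationary phase, at 65.0-fold, and BAG7, a GTPase-activating protein, at least 17.2-fold. SHH3, a homolog of a succinate dehydrogenase subunit, rose at least 14.9-fold and YNL194C, a membrane protein gene, at least 4.79-fold, while CDA1, for a chitin deacetylase, has a bound of only 1.09-fold. The falls at the top of the same ranking were the daughter-cell genes DSE2 (6221 ± 70.5 to 344 ± 46.3, 18.2-fold), SCW11 (at least 12.6-fold) and DSE1 (at least 3.79-fold), the mating-type switching endonuclease gene HO (at least 8.43-fold), AIM20 (at least 8.43-fold) and YGR035C (at least 14.7-fold).

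Of the genes tied to heme and oxygen, PUG1, a porphyrin transporter gene, rose 7.11-fold (83.1 ± 16.9 to 618 ± 285, adjusted p = 2.9e-04). UPC2, the activator of sterol uptake genes, rose 7.04-fold and AUS1, a sterol importer, 7.31-fold. HMX1, the heme oxygenase gene, rose 2.51-fold, HEM14 2.63-fold and HEM15 1.81-fold. YHB1, a flavohemoglobin gene, fell 8.24-fold (1980 ± 104 to 241 ± 19.5). COX5A, the aerobic form of a cytochrome oxidase subunit, fell 2.02-fold while its hypoxic counterpart COX5B rose 1.68-fold (adjusted p = 0.146 with median centring). HEM13, a classical hypoxic gene of heme synthesis, was at 663 ± 287 without and 640 ± 164 with ALA (log2 difference 0.00, SE 0.38, adjusted p = 0.995). ANB1 (0.44, SE 0.17, adjusted p = 0.056) and TIR1 (0.20, SE 0.15, adjusted p = 0.292) did not pass either, although both passed after quantile normalization (adjusted p = 0.0038 and 0.0013). CYC1, for cytochrome c, and CTT1, for a catalase, were dim in both hem1 groups. Of the sterol and lipid genes HMG2 rose 2.30-fold, ERG11 fell 1.68-fold, HMG1 fell 1.48-fold (adjusted p = 0.0852 without the arrays with a high 18S signal) and OLE1 did not pass (0.25, adjusted p = 0.219; 0.0140 after quantile normalization). DAN1 rose 3.18-fold, a call lost when some single arrays were left out. FET4, a metal transporter gene, rose 2.22-fold (adjusted p = 0.0817 with median centring). AAC3 (-0.40, adjusted p = 0.207), CYC7 (0.22, adjusted p = 0.418), FIT2 (-0.28, adjusted p = 0.238; 0.0104 as a fall with median centring) and ROX1, for the repressor of hypoxic genes (-0.33, adjusted p = 0.329), did not pass. ROX1 passed as a fall with median centring (adjusted p = 0.0447) and quantile normalization (0.0461). The probe sets of HAP1, the heme-responsive activator, disagreed: 1 rose by 2.01 on the log2 scale, and 2 fell, by 1.26 and 1.58. The names of the 2 that fell end in _f_at, like those of the near-identical seripauperins, so they may not read HAP1 alone. The brightest HAP1 probe set, which is given in the other comparisons, is 1 of these 2.

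Of the 7 DAN/TIR cell wall mannoprotein genes tested, 6 rose and 1 did not pass, as DAN4 at 14.6-fold and TIR3 at 8.07-fold (6 when adjusted over the list alone). All 10 seripauperin genes, a related family, rose, with a median of 31.5-fold (10 adjusted over the list alone). Among 8 sterol uptake genes 5 rose and none fell (5 adjusted over the list alone). Of 26 stress genes 22 rose, 1 fell and 3 did not pass (22 and 1 adjusted over the list alone), led by the chaperone genes SSA3 at 33.5-fold and SSA4 at 8.97-fold, while SOD2 fell 2.02-fold. Of 75 cytosolic ribosomal protein genes 58 fell and 1 rose (65 and 1 adjusted over the list alone), with a median log2 difference of -0.68, and of 31 ribosome biogenesis genes 27 fell (28 adjusted over the list alone), among them NOP56 at 2.55-fold. For gluconeogenesis and acetate use 8 of 11 genes rose and 1 fell (9 and 2 adjusted over the list alone), with PCK1 at 14.2-fold. For peroxisomal beta-oxidation 8 of 11 rose and 1 fell (the same adjusted over the list alone), with POT1 at 8.32-fold. Of 12 genes activated by heme through Hap1, 5 fell and 1 rose (the same adjusted over the list alone; 8 and 1 with median or quantile scaling); the one that rose, DLD1, encodes a lactate dehydrogenase, and 1 of the 5, CYC1, was dim in both groups.

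These lists passed camera with the preset correlation, as did the phosphate regulon and the MATalpha genes, 11 of 29 in all. With an estimated correlation none passed, and 5 had an unadjusted p under 0.05. The adjusted p was then 0.0779 for seripauperins and ribosome biogenesis, 0.0929 for ribosomal proteins and stress genes, 0.231 for DAN/TIR, sterol uptake, Hap1 and phosphate genes, and 0.242 for the rest. The Hap1 list also lost its call with median centring (adjusted p = 0.0734) and with spike scaling (0.0622). In total 3534 of 7081 probe sets changed, 2141 higher and 1393 lower, and 1461 and 650 of these by at least 2-fold. The share called higher, 60.6%, was 46.7% after quantile normalization, 36.8% after median centring and 44.7% with spike scaling. 1 array without ALA had a high 18S ribosomal RNA control signal (3507), and without it and its counterpart in hypoxia 2608 probe sets changed.

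**Figure D1:**
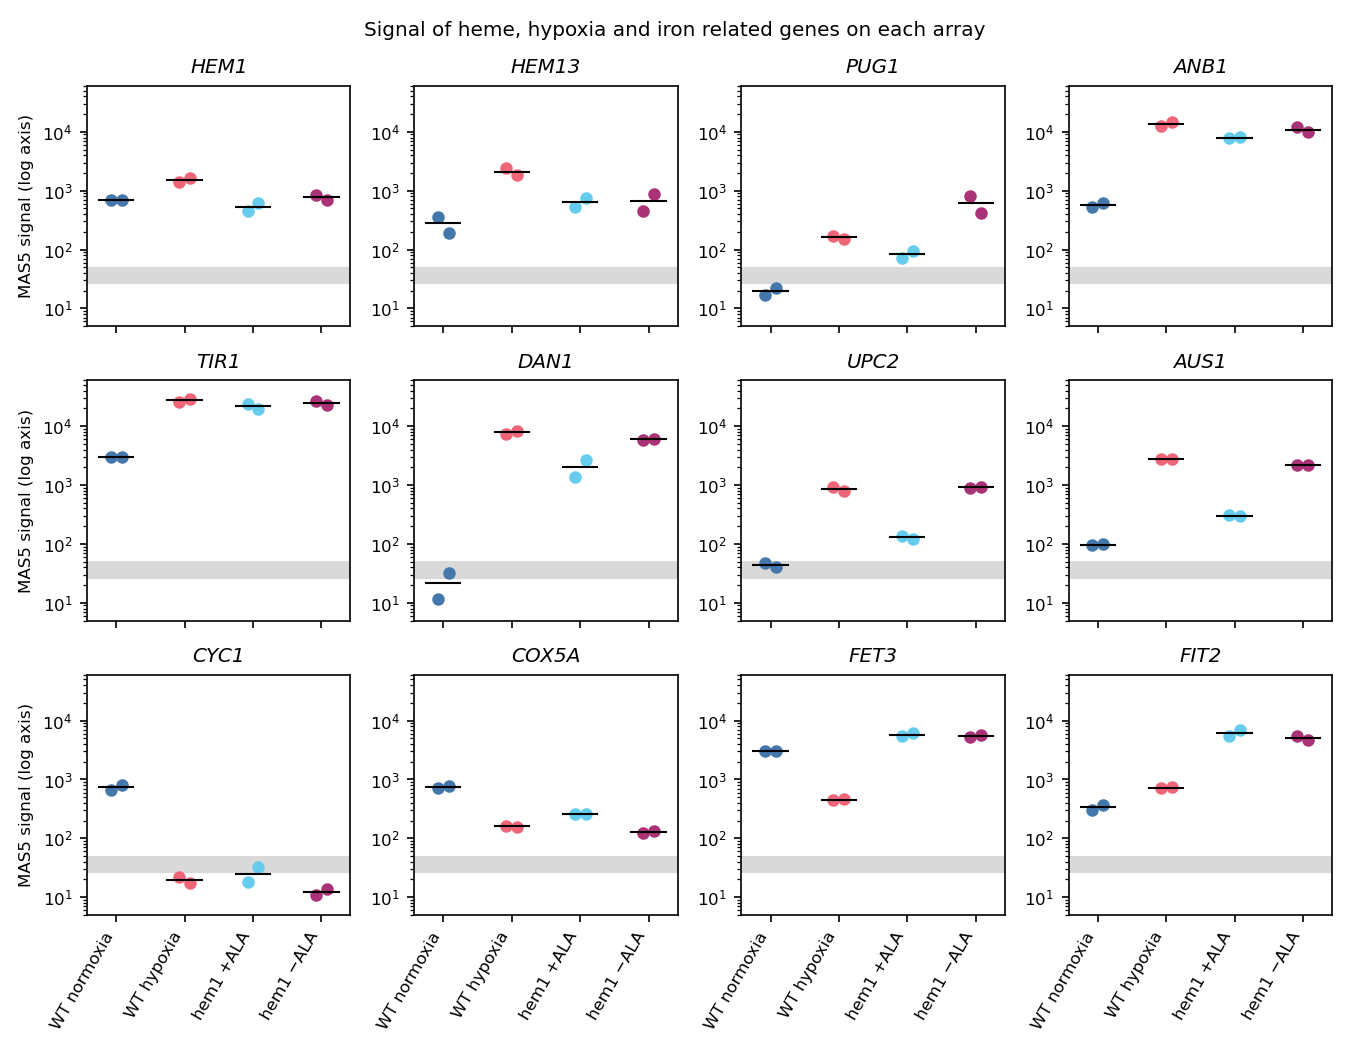
MAS5 signal (log axis) of 12 genes on each array by group, with points for arrays, black lines for means of 2 arrays and a grey band for the range of the arrays' 30th percentiles (26.6 to 48.7). ANB1 and TIR1 are higher in hypoxia and in both hem1 groups than in normoxia, CYC1 lies above the band only in normoxia, and FIT2 is brightest in the hem1 groups.

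The second comparison asks what hypoxia does in the wild type. The DAN/TIR and seripauperin genes, the genes of sulfate assimilation and methionine synthesis, and most hypoxic genes of the type repressed by Rox1 rose, while most ribosomal protein genes, all MATalpha genes and 11 of 25 respiratory genes fell. DAN1, an anaerobic mannoprotein gene, went from 22.1 ± 15.0, with 1 of 2 arrays above its 30th percentile, to 7876 ± 543 (at least 267-fold). TIR4 rose 132.9-fold, PBI1 at least 105.9-fold, HES1, an oxysterol-binding protein gene, at least 33.2-fold, and SHH3 at least 26.4-fold, with CDA1 at a bound of only 1.67-fold. The falls at the top of the ranking, again partly set by dim signals, were MF(ALPHA)2, a mating pheromone gene (5619.9 ± 144 to 108 ± 24, 52.6-fold), the cell wall genes CWP1 (32.2-fold) and UTR2 (31.0-fold), CYC1 (735 ± 105 to a dim 19.9 ± 3.3, at least 17.4-fold), TOS4 (at least 5.17-fold) and MDG1 (at least 4.40-fold).

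Among the Rox1-type genes 12 of 15 rose and none fell (12 adjusted over the list alone; 9 and 2 with median centring). ANB1, an anaerobic translation factor gene, rose 23.6-fold (574 ± 78.5 to 13507 ± 1655, adjusted p = 3.7e-07), TIR1 9.25-fold, HEM13 7.88-fold, AAC3 3.58-fold, FET4 2.69-fold, CYC7 2.10-fold and PUG1 at least 5.57-fold. COX5B rose 1.52-fold, a call lost with median centring (adjusted p = 0.631) and quantile normalization (0.0924), and OLE1 rose 1.54-fold, a call also lost with median centring (0.542). HEM1 rose 2.17-fold, HMG2 2.67-fold and FIT2 2.18-fold. HMG1 (-0.15, adjusted p = 0.400), HMX1 (0.48, adjusted p = 0.0904), the brightest HAP1 probe set (0.41, adjusted p = 0.102) and ROX1, dim in hypoxia (-0.52, adjusted p = 0.126), did not pass. The HAP1 probe sets disagreed here too. Another read 916 and 982 in hypoxia against 200 and 184 in normoxia, while the arrays of the third overlapped. With median centring HMG1 (adjusted p = 0.00568) and ROX1 (0.0110) passed as falls. All 7 DAN/TIR and all 10 seripauperin genes rose, as when adjusted over each list alone, with median folds of 44.4 and 150. Of 8 sterol uptake genes 7 rose and 1 fell (the same adjusted over the list alone): AUS1 rose 28.6-fold and UPC2 19.2-fold, while ARE2, for sterol esterification, fell at least 1.81-fold. Of 24 ergosterol genes 15 rose and 2 fell (the same adjusted over the list alone), with ERG28 up 3.29-fold and ERG4 down 4.13-fold. With median centring 5 rose and 3 fell and the list no longer passed (adjusted p = 0.0736), and ERG11, 1.77-fold higher, did not pass either (0.130).

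All 20 genes of sulfate assimilation and methionine rose (20 adjusted over the list alone; 19 with median centring), with MET2 at least 51.6-fold and STR3 17.8-fold higher. All 5 biotin genes rose (5 adjusted over the list alone; 3 with median centring), with BIO3 at 4.86-fold. Peroxisomal beta-oxidation genes rose in 10 of 11 cases (11 adjusted over the list alone; 5 with median or quantile scaling). Stress genes rose in 22 of 26 cases and fell in 2 (the same adjusted over the list alone; 15 and 2 with median centring), with HSP26 at 20.5-fold and SSA3 at 17.96-fold. Ribosomal protein genes fell in 61 of 75 cases and rose in 2 (the same adjusted over the list alone), with a median of -0.88, and ribosome biogenesis genes fell in 17 of 31 and rose in 1 (the same adjusted over the list alone). Of 25 nuclear respiratory genes 11 fell and 2 rose (the same adjusted over the list alone; 18 and 1 with median centring). COX5A fell 4.71-fold, and the members that rose were NDE2, an NADH dehydrogenase (at least 5.80-fold), and SDH2, a succinate dehydrogenase subunit (1.61-fold; adjusted p = 0.515 with median centring). Of 12 Hap1 genes 6 fell and 1, CTT1, rose (the same adjusted over the list alone), YHB1 falling 3.21-fold. The CTT1 call was lost with median centring (adjusted p = 0.128) and quantile normalization (0.148), where 9 and 8 Hap1 genes fell and none rose. Of 14 ATP synthase genes 5 fell (5 adjusted over the list alone; 8 with quantile normalization and 12 with median centring), and all 4 MATalpha genes fell (4 adjusted over the list alone). In glycolysis and fermentation 10 of 20 genes fell and 3 rose (the same adjusted over the list alone), ADH1 falling 2.31-fold, but the list passed neither with quantile normalization (adjusted p = 0.827) nor with median centring (0.0736). FET3, a multicopper iron oxidase gene whose product uses oxygen, fell 6.68-fold, and 9 of 27 iron regulon genes rose and 4 fell (5 and 8 with median centring; adjusted p of the list 0.693).

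In camera 16 of 29 lists passed with the preset correlation and none with an estimated one, where 12 had an unadjusted p under 0.05. The adjusted p was then 0.0811 for the DAN/TIR, seripauperin, Rox1-type, sterol uptake, sulfate, stress, respiratory and both ribosomal lists, 0.114 for ergosterol, Hap1 and peroxisomal genes, 0.127 for biotin and MATalpha genes, 0.132 for ATP synthase and 0.189 for glycolysis. In total 3954 probe sets changed, 2358 higher and 1596 lower, and 1695 and 821 by at least 2-fold. The share higher, 59.6%, was 43.9% after quantile normalization, 35.0% after median centring and 67.1% with spike scaling. The ACT1 3′/5′ control ratio, a measure of RNA quality, was 2.11 and 2.18 in hypoxia and 1.40 and 1.49 in normoxia, so it moved with all of these lists. Without the arrays with a high 18S signal (10736 on 1 hypoxia array) 2965 probe sets changed.

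**Figure D2:**
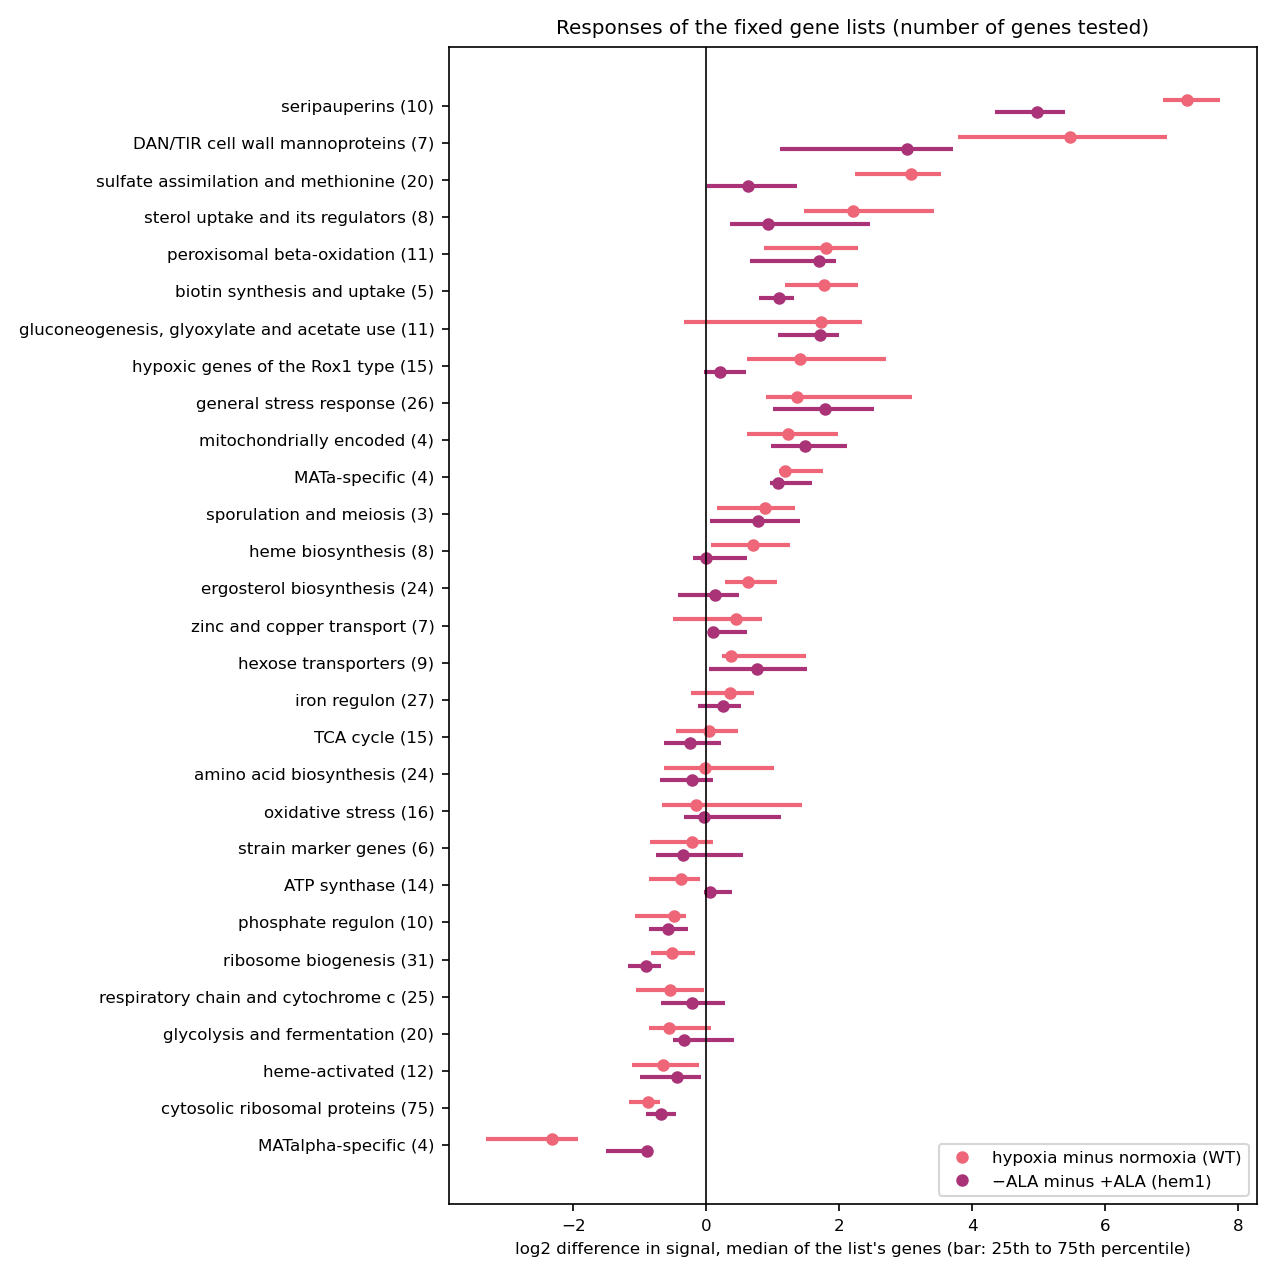
Median log2 difference in signal of the genes of each fixed list (number tested in brackets) in hypoxia and in heme depletion, with bars from the 25th to the 75th percentile of members. Seripauperin and DAN/TIR genes lie farthest to the right in both, sulfate and methionine genes lie at 3.08 in hypoxia and 0.63 in heme depletion, and ribosomal protein genes lie below 0 in both.

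The third comparison sets the responses side by side. Most genes called under both treatments moved the same way: 1514 probe sets rose in both (713 for independent lists), 852 fell in both (314), and 162 moved in opposite directions. Of the 2528 called in both, 93.6% shared their direction, and across 7081 probe sets the log2 differences correlated at a Pearson r of 0.73 and a Spearman rho of 0.68, across probe sets that are not independent. The treatments were applied to different strains for different times, 16 h and 12 h, so treatment, strain and time are confounded in the test of the difference. Without the arrays with a high 18S signal 1548 probe sets shared their direction, against 2366 with them.

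That test called 1257 probe sets, 599 with a higher and 658 with a lower log2 difference in heme depletion than in hypoxia. A signed difference can come from a smaller change, a larger one or an opposite one. Among the hypoxic and sterol genes the values were DAN1 -6.99 (SE 0.65; -6.03 with a floor for low signals), ANB1 -4.12 (SE 0.23), TIR1 -3.01 (SE 0.21), HEM13 -2.98 (SE 0.54), AAC3 -2.24 (SE 0.35), AUS1 -1.97 (SE 0.20) and UPC2 -1.45 (SE 0.24). A larger log2 rise need not mean a higher final signal. UPC2 read 909 and 928 without ALA and 910 and 807 in hypoxia, from 138 and 123 with ALA and 48.3 and 41.2 in normoxia. In the same order AUS1 read 2175 and 2229, 2804 and 2731, 305 and 297, and 94.8 and 98.6. HEM13 was lower without ALA (460 and 866) than in hypoxia (2406 and 1817). AUS1 and UPC2 rose under both treatments, and by more on the log2 scale in hypoxia, from a lower starting signal. So did DAN1, but its rise in heme depletion lost its call without either array without ALA (adjusted p = 0.0512 and 0.0572) and without replicate 1 with ALA (0.114). As scaled here ANB1, TIR1, HEM13 and AAC3 passed in hypoxia only, but AAC3 passed as a fall without ALA with median centring (-0.80, adjusted p = 0.0236) and quantile normalization (-0.72, adjusted p = 0.0442). ANB1, TIR1 and AAC3 were already high with ALA. ANB1 read 11879 and 9776 without ALA, 12336 and 14677 in hypoxia, 7713 and 8216.5 with ALA, and 518 and 629 in normoxia. In the same order TIR1 read 26946 and 23123, 25880 and 29300, 24136 and 19607, and 2941 and 3015. AAC3 read 273 and 404, 402 and 404, 365 and 527, and 121 and 104. ANB1 (adjusted p = 0.0038) and TIR1 passed as rises without ALA with quantile normalization. ERG11 (-1.57, SE 0.21) fell without ALA and rose in hypoxia. PUG1, dim in normoxia, did not pass (-0.21, SE 0.47, adjusted p = 0.792), and its direction turns with a floor (0.75, adjusted p = 0.296) and with quantile normalization (0.14). FET3 (2.68, SE 0.19) fell in hypoxia and did not pass without ALA (-0.06; -0.47 with median centring, adjusted p = 0.02002, and 0.14 with quantile normalization, adjusted p = 0.386). COX5A (1.22, SE 0.22) fell less without ALA than in hypoxia, a call lost with spike scaling (adjusted p = 0.0975). Without the arrays with a high 18S signal the differences of COX5A (adjusted p = 0.0597), HEM13 (0.0568), AAC3 (0.0510) and UPC2 (0.0570) did not pass. YHB1 (-1.36, SE 0.22) fell further without ALA. FIT2 (-1.40, SE 0.26) passed, but not without those arrays (adjusted p = 0.0632), and the brightest HAP1 probe set was at -1.67 (SE 0.27). Another HAP1 probe set was higher under both treatments: 1145.8 and 1150.5 without ALA against 283 and 287 with it, and 916 and 982 in hypoxia against 200 and 184 in normoxia. The third fell without ALA, like the brightest, and its arrays overlapped in hypoxia. The remaining fixed genes did not pass: HMX1 0.85, COX5B 0.15, ROX1 0.19, HMG1 -0.41, HMG2 -0.21, OLE1 -0.38, FET4 -0.28, HEM1 -0.58, CYC7 -0.85 and CTT1 -0.89.

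Of the largest differences, ECM13 (-5.84, SE 0.27) was lower without ALA (77.4 against 878 with it) and higher in hypoxia (454 against 91.0). CIP1, a cell cycle inhibitor gene (3.31, SE 0.26), was higher without ALA (264 against 141) and lower in hypoxia (124 against 652). YNR014W (3.77, SE 0.43) and ARO10, of amino acid breakdown (3.14, SE 0.34; dim with ALA), also had higher values in heme depletion. MET2, CIN1, YNL277W-A and UBC11 were dim in normoxia, so their sizes are not measured: with a floor MET2 was -4.70 and UBC11 -0.98, while CIN1 (-0.60, adjusted p = 0.186) and YNL277W-A (-0.17, adjusted p = 0.313) no longer passed. SLZ1 and YNL194C were 0.83 and 2.20 with a floor and did not pass without the arrays with a high 18S signal (adjusted p = 0.0922 and 0.147), and CYC1 passed (4.22) but was dim in both hem1 groups.

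By list, log2 differences were lower in heme depletion than in hypoxia for 18 of 20 sulfate and methionine genes and all 7 DAN/TIR genes. The same held for 9 of 10 seripauperins and 6 of 15 Rox1-type genes, and no member of these lists was higher. Adjusted over each list alone, 18, 7, 10 and 6 were lower. Values in this paragraph are such differences and not signals. TIR4 read 16799 and 15572 without ALA and 12702 and 15272 in hypoxia, while MET2 read 169 and 144 against 1396 and 1576. For hem1 with ALA minus normoxia the median log2 difference was 1.48 for DAN/TIR and 1.06 for seripauperin genes. It was 0.65 for Rox1-type and 0.25 for sulfate genes. All of these lists had smaller median rises without ALA (0.20 for the Rox1-type list, -0.20 with median centring). Their adjusted p was 0.0640 with an estimated correlation, and 0.0886 for the Rox1-type list. Of the sterol uptake genes (median 0.92 against 2.21 in hypoxia) 4 of 8, and of the ergosterol genes (0.13 against 0.62) 6 of 24, also had lower values (6 and 6 adjusted over each list alone; adjusted p = 0.103 for both with an estimated correlation). ATP synthase genes had higher values in 4 of 14 cases (10 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), with a median of 0.05 against -0.38 in hypoxia, and all 4 MATalpha genes fell less without ALA (4 adjusted over the list alone; 0.259 with an estimated correlation). Ribosome biogenesis genes were lower by median in heme depletion (-0.91 against -0.52), as were amino acid genes (-0.21 against -0.02), with 4 members of each passing (adjusted p = 0.103 and 0.283 with an estimated correlation). Respiratory genes were lower by median in hypoxia (-0.55 against -0.21 without ALA; adjusted p = 0.166 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.273) and spike scaling (0.0563). In all 11 of 29 lists passed with the preset correlation and none with an estimated one. The share of higher values, 47.7%, was 13.0% with spike scaling and 60.4% with 1 probe set per gene, and 533 probe sets passed without hypoxia replicate 1, 758 and 735 without either hem1 array with ALA, and 467 without the arrays with a high 18S signal.

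**Figure D3:**
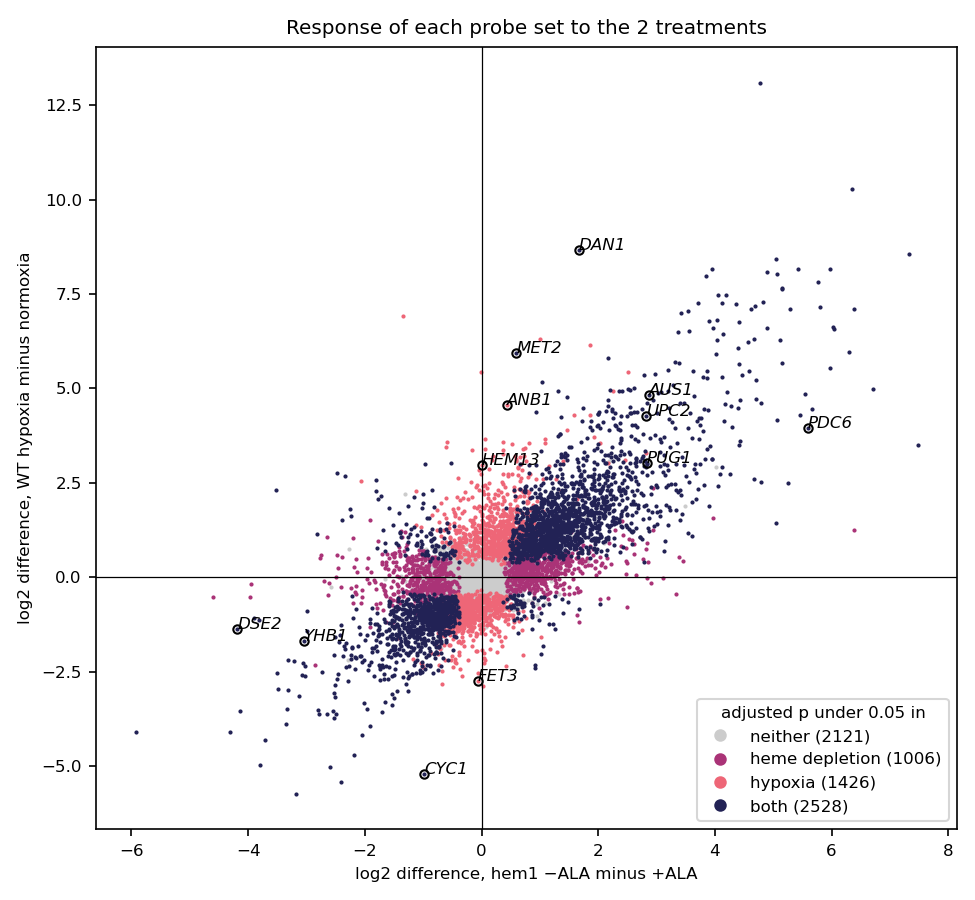
Log2 difference of each of 7081 probe sets in heme depletion (horizontal axis) and in hypoxia (vertical axis), coloured by the treatment in which it was called. The 2528 probe sets called in both lie mainly along the diagonal, while MET2, ANB1 and HEM13 lie near the vertical axis, and DAN1, called in both, lies at 1.67 and 8.66.

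The last comparison is between the control cultures, hem1 with ALA and wild type normoxia, which differ in strain, ALA, time and the order of array numbers. Most iron, DAN/TIR and seripauperin genes were higher in hem1 with ALA, as were 7 of 15 Rox1-type genes, and 16 of 25 respiratory genes were lower. Of 27 genes of the iron regulon controlled by Aft1, 24 were higher and none lower (25 adjusted over the list alone): FIT1, for a cell wall mannoprotein that retains siderophores, was at least 33.8-fold higher (1 of 2 normoxia arrays above its 30th percentile), FIT2 18.5-fold, HMX1 2.27-fold and FET3 1.91-fold. DAN1 was at least 64.2-fold higher (again 1 of 2 normoxia arrays), ANB1 13.9-fold (7965 ± 356 against 574 ± 78.5), TIR1 7.30-fold, AAC3 3.89-fold, AUS1 3.11-fold, UPC2 2.93-fold and HEM13 2.37-fold higher, the last lost with median centring (adjusted p = 0.0968) and quantile normalization (0.0908), while CYC7, also a hypoxic gene, was 2.24-fold lower. Of the DAN/TIR genes 6 of 7, of the seripauperins 8 of 10 and of the Rox1-type genes 7 of 15 were higher, and 1 Rox1-type gene was lower (7, 9, 7 and 2 adjusted over each list alone). Of the respiratory genes 16 were lower and 1 higher (19 and 1 adjusted over the list alone), CYC1 at least 20.1-fold and COX5A 2.92-fold, as were 6 of 12 Hap1 genes (6 adjusted over the list alone) and 3 of 4 mitochondrially encoded genes, though COB lost its call with a floor for low signals (adjusted p = 0.691). HSP42 was 7.05-fold lower. UBC11 was at least 2.60-fold higher, and SDH9 passed as lower (adjusted p = 0.0453) from signals too dim for a bound. Among the strain marker genes ADE2 was 2.03-fold lower, and TRP1, MET17 and HO did not pass. The ADE2 call was lost with spike scaling (adjusted p = 0.107) and when some single arrays were left out. Of the MATa genes MFA2 was at least 2.97-fold higher, and MFA1, BAR1 and STE6 did not pass. The probe sets of HIS3 disagreed, the brightest being 2.12-fold lower and the other not passing (adjusted p = 0.822). Of the fixed genes not yet named, PUG1 was at least 2.86-fold and FET4 2.62-fold higher (FET4 at adjusted p = 0.0667 without the arrays with a high 18S signal), and YHB1 was 1.62-fold lower (adjusted p = 0.324 with spike scaling). HEM1 (-0.40), COX5B (-0.37), CTT1 (-0.44), ERG11 (-0.02), HMG1 (-0.28), HMG2 (-0.06), OLE1 (0.39), ROX1 (0.65) and the brightest HAP1 probe set (0.62) did not pass.

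With an estimated correlation the iron and respiratory lists passed (adjusted p = 0.0212 for both). The adjusted p was then 0.0818 for the DAN/TIR, seripauperin and Hap1 lists, 0.174 for the Rox1-type list and 0.323 for the mitochondrially encoded one, of 12 lists that passed with the preset correlation. In total 1540 probe sets differed, 979 higher and 561 lower. The share higher, 63.6%, was 47.3% after quantile normalization, 35.9% after median centring and 91.8% with spike scaling, and 838 or 695 probe sets passed without either hem1 array with ALA.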

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

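All tests in this part were chosen after the result was seen. 4 values of ribosomal RNA control probe sets, which no comparison uses, stood above 4 times the highest control array of their experiment. On hem1 without ALA replicate 1 the 18S probe set a read 3717 and b read 3507, against at most 489 and 180 with ALA and 203 and 115 on the other array without ALA. On hypoxia replicate 2 they read 3492 and 10736, against at most 723 and 259 in normoxia and 651 and 355 on the other hypoxia array.

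Many hypoxic genes stood high, and many respiratory genes low, in hem1 cultures supplied with ALA compared with the wild type in normoxia. Array scaling is argued against: over the 21 DAN/TIR and Rox1-type genes the smallest median log2 difference under 4 scalings was 0.83, with a lowest bootstrap bound of 0.16. The bootstrap resampled genes, which are not independent, so it measures the spread among them and not between cultures. Incomplete restoration of heme by ALA is a hypothesis that stays open. The Hap1 list was lower, with a camera adjusted p of 0.00063 at the preset correlation and 0.0818 with an estimated one. The estimate was -0.048, below the preset 0.01, so correlated genes do not explain the higher p. The p with the estimate is limited by the few arrays, and the preset p treats genes as replicates, so the test cannot decide. An effect of strain or culture time cannot be told apart from incomplete restoration, because every hem1 culture differs from every wild type culture in both. The array titles share a tag and number the hem1 arrays before the wild type arrays, so array number goes with strain. Whether the arrays of the strains were run apart is not stated. An offset of equal size in both hem1 groups cancels in the difference of the responses, which is then near 0 only if the treatments act equally. Over the same genes the median difference was -1.57 (95% bootstrap interval over genes -2.52 to -0.28). Treatments of unequal strength, or an offset with a ceiling on the signal, could give a value below 0. The difference also contains the high control-culture difference of these genes with its sign reversed, which favours a value below 0. The test therefore cannot decide on an offset.

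Of 4 mitochondrially encoded genes tested 3 were lower in hem1 with ALA, 1 of which, COB, lost its call with a floor for low signals (adjusted p = 0.691). Complete loss of mitochondrial DNA is argued against, since 2 of these genes, OLI1 and COX1, lay above the 30th percentile on all 4 hem1 arrays (OLI1 at 998 to 5500, COX1 at 231 to 639), although other probe sets of both genes were dim on these arrays. Partial loss was not tested.

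Most stress genes rose and most ribosomal protein genes fell under both treatments. Array scaling is argued against: under 4 scalings the smallest median of the stress list was 0.87 (lowest bootstrap bound 0.48) and the highest of the ribosomal protein list was -0.49. The bootstrap again resampled genes and not cultures. For heme depletion the ACT1 3′/5′ ratio gave no sign of a shift in RNA quality. Its log2 value differed by 0.069, less than the largest difference between replicates (0.247). That is 1 transcript. For SPT15, another control, the ratio was 3.52 and 1.96 without ALA and 2.28 and 3.66 with ALA. With the high 18S signal on 1 array without ALA, other differences in RNA quality stay open. In hypoxia the log2 ACT1 ratio differed by 0.574, so RNA quality cannot be told apart from the treatment there. Slower growth in both treatments is an untested biological explanation.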

How the results depend on the processing

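Scaling to the spikes and leaving out the 2 arrays with high 18S signal were chosen after the data were seen. Over 289 results for named genes and 20 alternative settings, 5383 of 5711 values kept direction and side of the threshold. Of the rest 242 fell short of it, 32 newly passed, and 53 that did not pass as reported changed sign. Only 1 that passed reversed: PHO81 in hypoxia, at 0.45 as reported, was -0.037 with median centring (adjusted p = 0.837), where each array's own median shift is removed. In all, 194 results stayed as reported under every setting run. With an estimated correlation 0 lists passed in heme depletion and 0 in hypoxia. Counts of at least 2-fold calls with 1 probe set per gene were 552 for the control cultures (850 as reported) and 665 for the difference of the responses (1022), with fewer probe sets tested. With spike scaling 1453 control-culture calls were at least 2-fold. Without the 2 arrays with high 18S signal, the difference of the responses gave 467 calls, all 467 at least 2-fold, and shared calls numbered 1548 (2366 as reported), with fewer samples. The cause of the other moves was not tested. Leaving out single arrays, with the lone array assumed to vary like the others, gave 2658 to 3662 calls for heme depletion (1955 to 2139 at least 2-fold), 3080 to 3990 for hypoxia (2246 to 2566), 695 to 1514 for the control cultures (585 to 873), 533 to 1089 for the difference of the responses (518 to 1026), 1868 to 2255 shared calls, 10 to 12 lists in heme depletion and 15 to 17 in hypoxia. The low ends were reached without hem1 with ALA replicate 2 for the control cultures (695; 838 without replicate 1) and without hypoxia replicate 1 for the difference of the responses (533; 758 and 735 without hem1 with ALA replicates 1 and 2). Signals below the arrays' 30th percentiles limit folds to bounds.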

Other observations

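Many cell-cycle genes were lower. Lists of G1/S, G2/M and daughter-cell separation genes were written after the named genes were seen, so they restate part of that choice and their p-values are no independent test. Of 21 G1/S genes 9 fell and 1 rose in heme depletion (14 falling with quantile normalization, 15 with median centring and 12 with spike scaling), and 15 fell in hypoxia, among them RNR1, for ribonucleotide reductase (6.28-fold and 12.3-fold), and POL30, for the replication clamp (6.93-fold and 12.3-fold). Of 7 G2/M genes 6 fell in each, as CLB1 at 11.2-fold and 7.71-fold. Of 10 daughter-cell genes 9 fell and 1 rose in heme depletion. In hypoxia 5 fell and 2 rose (7 and 8 falling with quantile and median scaling), and the list did not pass even with the preset correlation (adjusted p = 0.0508). With an estimated correlation, adjusted over these lists, p was 0.0847 and 0.0562 for G1/S, 0.0276 and 0.0562 for G2/M, and 0.0276 and 0.185 for daughter-cell genes.

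As scaled here the lists named next did not pass, except the phosphate regulon in heme depletion, and the balance of several turns with median centring, whose counts are given in brackets as rose and fell. In the phosphate regulon 1 of 10 genes rose and 5 fell in heme depletion (1 and 9), and 2 rose and 5 fell in hypoxia (1 and 8), with SPL2 and VTC3 falling 4.43-fold and 3.27-fold in heme depletion while PHO89, a phosphate transporter gene, rose 4.34-fold and 9.48-fold. Of 9 hexose transporter genes 5 rose in each (3 and 1; 3 and 2), RGT2 at 3.79-fold and 4.04-fold, and this list did pass after quantile normalization (adjusted p = 0.0242 and 0.0277). Of 16 oxidative stress genes 5 rose and 2 fell in heme depletion (5 and 8), and 6 rose and 6 fell in hypoxia (5 and 8). In the TCA cycle 2 of 15 genes rose and 5 fell (1 and 7), and then 3 rose and 5 fell (1 and 6), with ACO1 falling 4.64-fold without ALA. Of 24 amino acid synthesis genes 2 rose and 7 fell (2 and 12), and then 9 rose and 6 fell (6 and 10), ARG1 rising 5.40-fold in hypoxia. Of 7 zinc and copper genes 2 rose and 1 fell (1 and 1), and then 2 rose and 2 fell (1 and 3), CTR1 falling 3.99-fold in hypoxia. Of 8 heme synthesis genes 3 rose and 1 fell (2 and 3), and then 5 rose and 1 fell (3 and 1).

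In heme depletion 6 of 24 ergosterol genes rose and 6 fell (with median centring 4 rose and 9 fell), 10 of 20 sulfate genes rose and 2 fell (8 and 2), 3 of 5 biotin genes rose (3 and 0), and 3 of 20 glycolysis genes rose and 7 fell (2 and 13). Of 15 Rox1-type genes 4 rose and 1 fell (2 and 4, and 8 and 3 with quantile normalization), of 25 respiratory genes 4 rose and 6 fell (1 and 12), of 14 ATP synthase genes 4 rose and 1 fell (2 and 4), and of 27 iron genes 5 rose and 2 fell (3 and 6). In hypoxia 7 of 11 genes of gluconeogenesis rose and 3 fell (6 and 3). Their median log2 difference was 1.72, but 0.76 with dim signals set to bounds. Of 4 mitochondrially encoded genes tested 3 rose and then 2 (2 and 0 in each), but COB, 1 of the 3, was dim in both hem1 groups. Of 4 MATa genes 2 rose and then 4 (1 and 0 in each, also with quantile normalization), BAR1 reaching 152 without ALA and 129 in hypoxia. Of 3 sporulation genes tested 2 rose and then 1 (1 and 0; 1 and 1), and of 6 strain marker genes 1 rose and 2 fell and then 1 rose and 1 fell (0 and 3; 1 and 4).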
